A study of Mus musculus with 2 samples.

How the data were processed

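Hippocampal RNA from 3 kinds of mice was measured on 2 two-colour oligonucleotide arrays: wild type, AtrxdE2 (mice that carry the AtrxΔE2 allele of the chromatin remodeller gene Atrx) and AtrxdE2 given TMPyP4, a porphyrin that binds G-quadruplex DNA. Per the labels, each RNA was a pool of 5 mice, TMPyP4 was given intraperitoneally at 30 mg/kg with 2 injections a week from postnatal day 30 to day 90, and amino allyl RNA was labelled with Cy5 for wild type and Cy3 for the mutant pool on both arrays. One array therefore carries AtrxdE2 against wild type and the other AtrxdE2+TMPyP4 against wild type. Dyes were not swapped, so a probe's dye bias drops out of the difference of both ratios over wild type only where it is equal on both arrays. Whether it was equal was not tested. Whether the wild-type RNA was 1 pool on both arrays is not stated.

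The deposited scanner tables hold, per the file headers, the median intensity of each spot in both channels, merged from several scanner gains, with the local background intensity and quality marks. The scanning software and its version are not given in the sources used here. The authors' value table holds, per the labels, normalized log2 ratios of mutant over wild type. Its background step, centring and missing-value rule were unstated and were recovered from the scanner values: each value equals the log2 ratio of Cy3 over Cy5 after subtraction of the trimmed mean of the array's blank spots, minus a constant of 0.65 on the AtrxdE2 array and 1.17 on the AtrxdE2+TMPyP4 array. This held within 0.01 for 99.99% of the values of each array, with r = 0.99997, and it settles the direction. A value is missing where a channel did not exceed the blank mean by 2 SD, a rule that matched 99.97% of probes. The median of each column is 0.0.

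Each array has 27456 spots, of which 2736 are blank, and 23473 probes. The platform annotation names 1 gene for 16631 probes, several for none, and leaves 6842 unnamed here. Of the 16446 distinct symbols, 12501 are current in the RefSeq gene table of assembly GRCm38.p6, 3883 matched 1 current gene through a synonym and 62 matched none. Symbols are printed as the annotation gives them, with the current symbol beside older ones. No coordinates were used.

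Background was corrected with the normexp method of limma 3.58.1 (R 4.3.3) with an offset of 50, taking the trimmed mean of the blank spots (without a share of 0.05 at each end) as the background level, and each array was then normalized by loess with control spots at weight 0. The local background was not used as the main level because it rose with the spot's own intensity (log-scale r between 0.901 and 0.985) and exceeded the spot in 22.9% of probes in the Cy5 channel of the AtrxdE2+TMPyP4 array. This choice was made after seeing the data. A probe counted as measured when it was not marked bad and lay above the blank mean plus 2 SD in both channels of both arrays, which left 18664 probes and 13630 named genes. Probes of one gene were averaged. In 127 genes with several measured probes, the median range between probes was 0.15 log2 units for AtrxdE2 over wild type, 0.13 for AtrxdE2+TMPyP4 over wild type and 0.19 for the difference.

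The main normalization compressed the ratios of dim probes in simulated data. In data simulated on the AtrxdE2 array, a log2 ratio of 2 was recovered with a median of 1.33 over all measured probes and of 1.79 over bright ones, and on the AtrxdE2+TMPyP4 array with medians of 1.27 and 1.90. A log2 ratio of -2 was recovered with medians of -1.24 and -1.64 on the AtrxdE2 array and of -0.74 and -1.62 on the AtrxdE2+TMPyP4 array. Past 2-fold were 66% of probes simulated at 2 and 59.1% at -2 on the first array, and 61.2% and 38.5% on the second. Ratios from the authors' value table, which has neither offset nor loess, are printed beside the main ones for some genes. Of 231 log2 ratios of genes that are always named or stand at the ends of comparisons and lists, 75 were over 1.5 times larger in that table and 2 had the opposite sign. Simulated lists of 15 genes shifted by 0.2 were placed in the outer 5% of random lists in 99 of 100 cases, and unshifted lists in 2 of 100. Their genes were drawn at random from shuffled values and were therefore independent. Where members of a real list vary together, these shares and the number of lists expected by chance need not hold.

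With 1 array of 1 pool per group there is no replicate error, so no p-value was computed. Probes were counted by a fixed rule of 2-fold. Each named gene is set against the SD of the log2 ratios of the 500 genes nearest in signal. For 46 of 47 gene lists fixed before the data were examined (29 pathways and 18 sets of cell type markers), the median log2 ratio was placed among 10000 random lists of the same size matched on signal in 20 bins, as a description of these arrays. The list of the Xlr cluster had under 4 measured genes and has values only. Repeated positive control spots, 24 of each of a pair of controls, varied with an SD between 0.087 and 0.11 log2 units within an array. Their mean log2 ratios were 0.12 and -0.54 on the AtrxdE2 array. On the AtrxdE2+TMPyP4 array they were -0.16 and -0.44, so the same control gave different ratios on the arrays.

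Genes are named by a rule fixed beforehand: Atrx, Daxx and the Xlr genes always; for each comparison the 10 highest and 10 lowest genes with an official-style symbol; 5 genes per direction that were above background in only one RNA; and 2 members at each end of lists in the outer 5% of random lists and of several preset lists. For a probe above background in only one RNA, the fold is a lower bound, taken after loess and Aquantile normalization against the higher of the dim signal and the lowest signal above background in that channel, and it is open to dye bias. Alternatives fixed beforehand were centring on the median without loess, the authors' value table, plain background subtraction with no offset, all probes, probes above the median signal, a rule of 1.5-fold, direct comparison of the Cy3 channels, and for lists the brightest probe per gene and random lists not matched on signal. Local background, leaving out the choroid plexus and meninges lists, and plain subtraction for lists, overlap, shares and the correlation were added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.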

Results

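Gene expression in the hippocampus was compared between wild-type mice, AtrxdE2 mice and AtrxdE2 mice treated with TMPyP4, each represented by 1 pool of RNA from 5 animals. Both mutant pools were hybridised against wild type, 1 array each, so no value below has a replicate check and no p-value is given. The median signal above the blank spots was 42.2 for wild type and 64.6 for AtrxdE2 on the first array, and 36.02 for wild type and 79.0 for AtrxdE2+TMPyP4 on the second. The blank spots varied with an SD of 1.23 and 3.30 in these channels of the first array, and of 0.92 and 3.27 in those of the second. Both channels were above background for 84.5% and 81.1% of probes. The number of arrays limits the precision of every value. Across the 18664 measured probes, the wild-type channels of the arrays correlated with r = 0.985 after quantile normalization and differed with an SD of 0.27 log2 units, and 102 probes (0.547%) differed by at least 2-fold. The Cy3 channels, which hold the mutant pools, correlated with r = 0.973, differed with an SD of 0.41, and 536 probes (2.87%) differed by at least 2-fold. Wild type was always Cy5 and the mutant pools always Cy3, so dye and group cannot be told apart in this contrast.

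The first comparison asks how the hippocampal transcriptome of AtrxdE2 mice differs from wild type. Atrx itself had a log2 ratio of -0.68 over wild type, with a signal above blank of 19.1 in AtrxdE2 and 47.4 in wild type, and -1.96 in the authors' value table. The 500 genes nearest in signal had an SD of 0.15, and Atrx lay at their percentile 0.1. The position of this probe relative to the deleted exon was not analysed here. Xlr3b, a member of an X-linked gene cluster, had the highest ratio of all named genes, at 1.75 (2.47 in the authors' value table), with signals of 433.8 in AtrxdE2 and 49.9 in wild type, and an SD of 0.21 among genes nearest in signal. Xlr4b had 0.33 (0.84 in the authors' value table, percentile 98.1 among genes nearest in signal) and Daxx, which encodes the histone chaperone partner of ATRX, 0.14 (percentile 74.5). Xlr5d was not above background in any channel. Other genes of the Xlr cluster list were not analysed here.

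At least 2-fold differences were found at 12 probes that were higher and 4 that were lower in AtrxdE2, of which 8 and 3 are unnamed here. Named probes on the higher side belonged to Xlr3b, Ttr, Mgp and Eif3s1 (now Eif3j1, whose 3 probes disagreed and averaged 0.44), and the single named probe on the lower side to Mbp, which encodes myelin basic protein. Ttr, which encodes the thyroid hormone carrier transthyretin of the choroid plexus, had a log2 ratio of 1.59 (2.34 in the authors' value table). Its signals before normalization were 352.6 in AtrxdE2 and 44.3 in wild type. On the other array wild type had 219.4, so the wild-type signal of this gene itself differed widely between arrays. Ttr was followed by the matrix protein gene Mgp with 1.02, Ankhd1 with 0.99, the corepressor gene Ncor1 with 0.97, the ceruloplasmin gene Cp with 0.96 (1.53 in the authors' value table), the adhesion molecule gene Chl1 with 0.88, the channel gene Trpc6 with 0.85, the fibronectin gene Fn1 with 0.84 and Zcchc7 with 0.81. At the lower end, Mbp had -1.32 and the myelin gene Mobp -0.98. Wbscr1 (now Eif4h) had -0.97, the enkephalin precursor gene Penk1 (now Penk) -0.97, Slc22a17 -0.96, the small heat shock protein gene Cryab -0.96, Idi1 of isoprenoid synthesis -0.94, Ppp1r1b -0.90, the chaperone gene Hspa8 -0.86 and the protein kinase A subunit gene Prkacb -0.85. The SD among genes nearest in signal lay between 0.20 and 0.26 for these genes. Wild-type signals before normalization differed widely between the arrays for Penk1 (1483.9 and 688.9, against 1149.8 in AtrxdE2). The same held for Ppp1r1b (3448.3 and 1444.7, against 2777.5). For this pair the fall in AtrxdE2 therefore depends on which wild-type value is used.

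Of 46 gene lists, 8 had a median in the outer 5% of random lists in this comparison, against 2.3 expected by chance for independent genes. All 14 measured oligodendrocyte genes were below 0, with a median of -0.49 (SD 0.32 over genes, percentile 0.0), from Mbp at -1.32 to Hapln2 at -0.14 and Ugt8a at -0.12. Cholesterol synthesis had a median of -0.19 (SD 0.26, percentile 0.1), with 13 of 17 genes below 0 and with Idi1 at -0.94 and Sc5d at -0.65. Immediate early genes, which respond to neuronal activity, had a median of -0.09 (SD 0.28, percentile 0.93), with 23 of 33 below 0. Junb was at -0.83 and Sgk (now Sgk1) at -0.63, while Btg2 was at 0.42 and Jun at 0.33. Imprinted genes had a median of -0.075 (SD 0.21, percentile 2.44), from Nap1l5 at -0.44 and Peg3 at -0.34 to Impact at 0.56 and Igf2 at 0.29. On the higher side, meninges and fibroblast genes had a median of 0.37 (SD 0.29, percentile 100), with 13 of 14 above 0 and with the collagen gene Col1a2 at 0.73. Pericyte and smooth muscle genes had 0.19 (SD 0.22, percentile 99.9), with 11 of 12 above 0, including Tagln at 0.57 and Acta2 at 0.39. The 4 measured blood genes had a median of 0.33 (SD 0.35, percentile 99.99; 1.065 in the authors' value table), with S100a9 at 0.74 (2.02 there), S100a8 at 0.42, Ngp at 0.24 and Alas2 at -0.093. Interferon response genes had 0.073 (SD 0.16, percentile 99.6), with 19 of 29 above 0, among them Irf1 at 0.35 and Gbp2 at 0.33, with Ifit3 at -0.40 and Mx1 at -0.16. Imprinted genes left the outer 5% with median centring (percentile 4.99) and among probes above the median signal (16.6), and interferon genes among the latter (96.3).

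Preset lists inside the middle 95% of random lists in AtrxdE2 over wild type included Atrx and its partners, with a median of 0.083 (SD 0.27, percentile 92.2), Cbx5 at 0.33 and Setdb1 at 0.23, and the histone gene H3f3a at -0.37. CaMKII and calcium signalling genes had 0.072 (SD 0.26, percentile 96.5), from Camkk2 at 0.42 and Cacna1h at 0.40 to Calm2 at -0.31, and lay in the outer 5% with plain background subtraction (97.94), among probes above the median signal (98.4) and against random lists not matched on signal (98.72). Heme and porphyrin genes had -0.083 (SD 0.22, percentile 5.76), with Tfrc at 0.41 and Alas1 at 0.17, and the ferritin genes Fth1 at -0.58 and Ftl1 at -0.46, and lay at percentile 2.41 of unmatched random lists. The choroid plexus list had a median of 0.046 (percentile 88.0), Ttr aside with Kl at 0.30 at the upper end and Kcne2 at -0.15 and Sostdc1 at -0.14 at the lower end. Its median was 0.165 in the authors' value table, in the outer 5% (percentile 98.3), and -0.075 with median centring (percentile 30.2). Among probes above background in only AtrxdE2, the highest bound was at least 1.24-fold for Usp52 (now Pan2), followed by Serpina3g with 1.23, Tigd4 with 1.18, Tshr with 1.17 and Whrn with 1.16. Among those above background in wild type only, it was at least 1.23-fold for Nuak1, then 1.21 for Pip5k2b (now Pip4k2b), 1.19 for Olig3 and 1.14 for Ifne1 (now Ifne) and Lrrc16 (now Carmil1). In the authors' value table, which differs in background correction, offset and centring, 219 probes were higher and 148 lower.

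**Figure D1:**
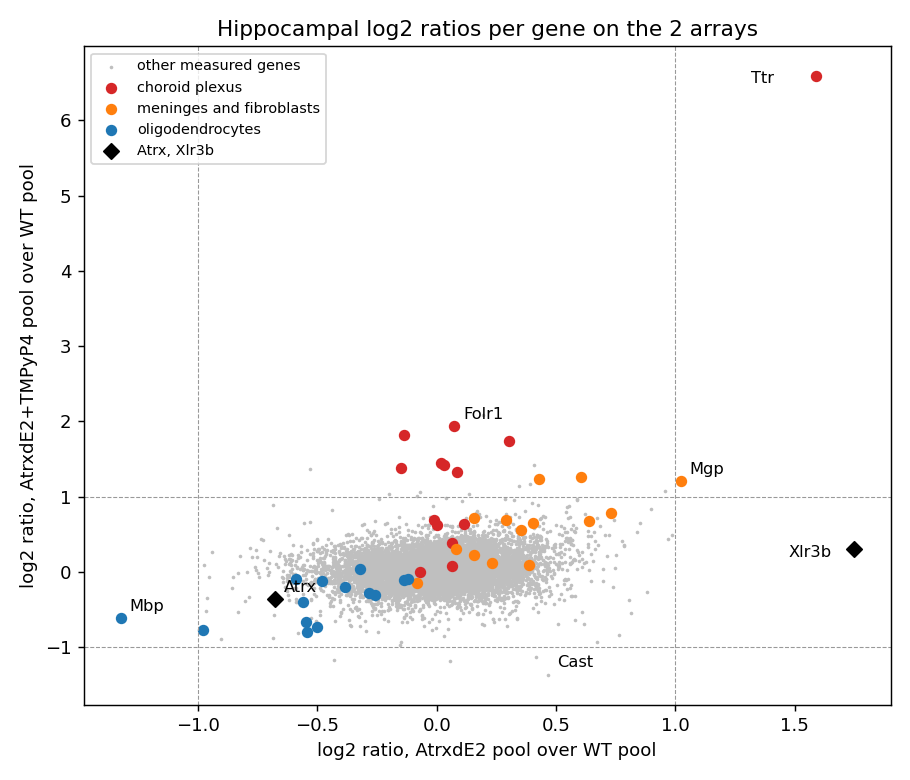
Each point is a measured gene, placed by its log2 ratio over wild type in AtrxdE2 (horizontal axis) and in AtrxdE2+TMPyP4 (vertical axis), with dashed lines at 2-fold. Coloured points are members of the choroid plexus, meninges and oligodendrocyte lists, and black diamonds are Atrx and Xlr3b. Ttr lies at 1.59 and 6.59, Xlr3b at 1.75 and 0.30, and Mbp at -1.32 and -0.61.

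The second comparison sets the TMPyP4-treated AtrxdE2 pool against wild type. Genes of the choroid plexus, the secretory epithelium of the brain ventricles, stood out: 8 of the 14 measured list members were at least 2-fold higher and 13 were above 0, with a median of 1.35 (SD 1.62 over genes, percentile 100; 2.36 in the authors' value table). Ttr had a log2 ratio of 6.59 (6.94 in the authors' value table), with signals of 60792 in the treated pool and 219.4 in wild type. The folate receptor gene Folr1 had 1.93, Sostdc1 1.82, the klotho gene Kl 1.74, Clic6 1.44, Calml4 1.42 and the potassium channel subunit gene Kcne2 1.38, against 6.0, 3.79, 3.25, 3.38, 3.69 and 3.46 in the authors' value table. Guca1a with 1.97, Rspo1 with 1.42 and Cap1 with 1.36 completed the highest genes, and Ace, close to 0, was the lowest of the choroid plexus list. The SD of genes nearest in signal lay between 0.15 and 0.37.

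In all, 27 probes were at least 2-fold higher and 13 lower in AtrxdE2+TMPyP4, and 5 and 9 of them are unnamed here. Without the choroid plexus and meninges lists, 16 were higher and 13 lower. The lowest named genes were Cast, which encodes the calpain inhibitor calpastatin, with -1.37, the imprinted noncoding RNA gene Gtl2 (now Meg3) with -1.18, the retinoid X receptor gene Rxrg with -1.17 and the collagen gene Col6a1 with -1.13. Hap1 had -0.97, the glutamine synthetase gene Glul -0.93, Ppp1r1b -0.89, the cyclophilin gene Ppia -0.88, Six6os1 (now 4930447C04Rik) -0.86 and R3hdm1 -0.84. Atrx had -0.36 (-0.78 in the authors' value table, percentile 1.3 among genes nearest in signal), with signals of 71.5 in the treated pool and 54.6 in wild type before normalization. Xlr3b had 0.30 (0.46 in the authors' value table, percentile 90.7), Xlr4b -0.035 (percentile 32.3) and Daxx -0.094 (percentile 31.9).

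In this comparison 13 of 46 lists had a median in the outer 5% of random lists, against 2.3 expected by chance for independent genes. Meninges and fibroblast genes had a median of 0.67 (SD 0.44, percentile 100), with 13 of 14 above 0 and with Crabp2 at 1.26, Ogn at 1.23 and Mgp at 1.21. Oligodendrocyte genes were again low, with a median of -0.29 (SD 0.29, percentile 0.0) and 13 of 14 below 0. Cnp1 (now Cnp) was at -0.80, Mobp at -0.78, Mbp at -0.61 and Mag at 0.034. Oligodendrocyte precursor genes had -0.16 (SD 0.19, percentile 0.13), with 10 of 11 below 0, including Bcas1 at -0.56 and Sox10 at -0.50. Striatal marker genes had -0.50 (SD 0.35, percentile 0.0), with 8 of 11 below 0, Ppp1r1b at -0.89 and Rgs9 at -0.76, and with Tac1 at 0.14 and Pdyn at 0.13. Cell cycle and neurogenesis genes had -0.08 (SD 0.22, percentile 0.04), with Aurkb at -0.45, Top2a at -0.42 (-2.02 in the authors' value table), Neurod1 at 0.48 and Pcna at 0.38, and their median was 0.12 among probes above the median signal. Genes of CA1 pyramidal neurons had -0.25 (SD 0.35, percentile 0.04), from Nov (now Ccn3) at -0.33 to Dcn at 0.71, and microglial genes -0.11 (SD 0.11, percentile 1.24), from Tyrobp at -0.26 to Siglech at 0.16. Dcn is also a member of the meninges and fibroblast list. With median centring in place of loess the CA1 and microglial medians were 0.12 and 0.20 (percentiles 3.14 and 20.8), and in the authors' value table the microglial list lay at percentile 3.68.

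Several lists were higher in AtrxdE2+TMPyP4 than in wild type. Oxidative phosphorylation genes had a median of 0.095 (SD 0.22, percentile 99.8), with 31 of 50 above 0, Cycs at 0.51 and Ndufs3 at 0.45, and with Cox4i1 at -0.39 and Ndufa4 at -0.36. Unfolded protein and integrated stress response genes had 0.13 (SD 0.21, percentile 99.1), with 18 of 23 above 0, led by Sdf2l1 at 0.48 and Dnajb9 at 0.43, and left the outer 5% with plain background subtraction (percentile 97.34). Telomere maintenance genes had 0.19 (SD 0.29, percentile 99.5), with Nola2 (now Nhp2) at 0.73 and Pot1 (now Pot1a) at -0.11, and thalamus and habenula genes 0.15 (SD 0.39, percentile 99.3), from Rora at 0.55 and Slc17a6 at 0.52 to Prkcd at -0.79 and Zic1 at -0.57. The 4 blood genes had a median of -0.12 (SD 0.082, percentile 1.1; -0.31 in the authors' value table), from S100a9 at -0.20 to Ngp at -0.022. With median centring the telomere list (percentile 94.9), the thalamus list (72.7) and the blood list (5.54) left the outer 5%, as did the blood list in the authors' value table (4.82), with plain subtraction (7.09) and against unmatched random lists (5.52), and the thalamus list among probes above the median signal (95.9). Immediate early genes lay inside the middle 95% (median -0.053, percentile 3.58, with Ier5 at 0.66, Bdnf at 0.41, Egr2 at -0.65 and Fos at -0.61). They lay in the outer 5% in the authors' value table (median -0.21, percentile 0.02), with plain subtraction (median -0.147, percentile 0.48), with median centring (percentile 0.03) and against unmatched random lists (1.56). Lists inside the middle 95% also included CaMKII and calcium signalling (median 0.052, percentile 88.5, with Ppp3cb at 0.53 and Camk2b at -0.49). The same held for heme and porphyrin metabolism (median 0.03, percentile 61.5, with Blvra at 0.47 and Fth1 at -0.81), imprinted genes (median -0.029, percentile 13.3, with Dcn at 0.71, Igf2 at 0.69 and Gab1 at -0.59) and Atrx and its partners (median -0.066, percentile 9.51, with Hira at 0.11 and Trim28 at -0.21). Dcn and Igf2 are also members of the meninges and fibroblast list.

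Above background in AtrxdE2+TMPyP4 but not in wild type were the claudin gene Cldn2, at least 2.22-fold higher, Tspan8 with 1.5, the coagulation factor gene F5 with 1.44, Krt28 with 1.3 and Defb10 with 1.28. Cldn2 and F5 belong to the choroid plexus list but were outside its measured members. In the opposite direction the bounds were at least 1.22-fold for Cxcl5, 1.16 for Tcfl5, 1.14 for Crabp1 and 1.13 for Sox11 and Cxcl10. Median centring without loess gave 91 probes higher and 1 lower, and in the authors' value table there were 311 and 143.

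**Figure D2:**
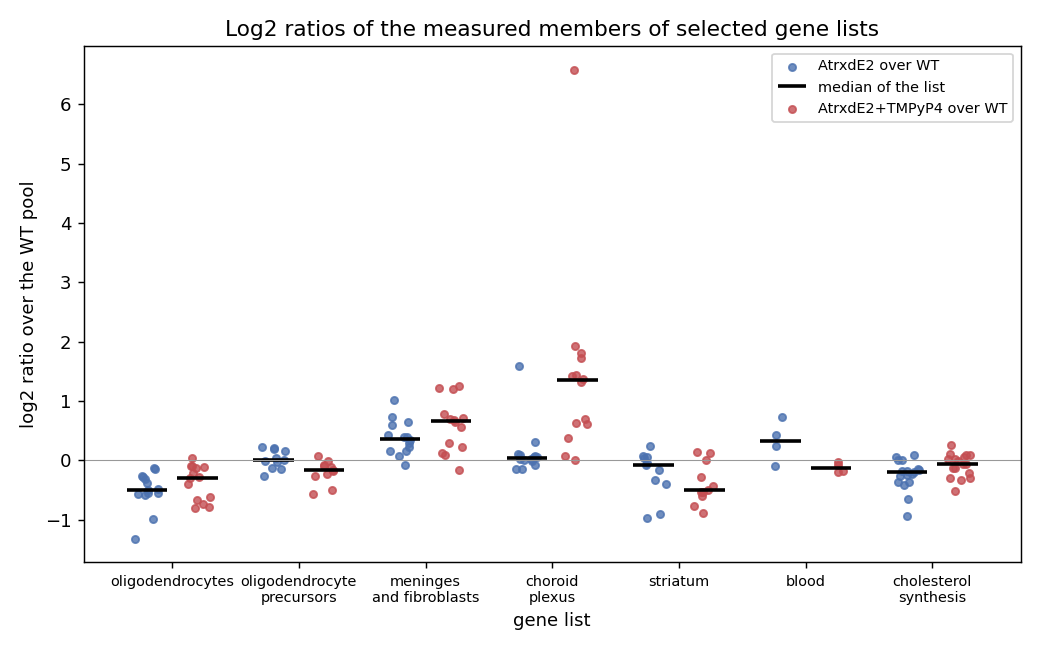
Points are the log2 ratios over wild type of the measured genes of selected lists, in AtrxdE2 (blue) and AtrxdE2+TMPyP4 (red), and black bars are the medians of each list. Oligodendrocyte medians are -0.49 and -0.29, meninges medians 0.37 and 0.67, and choroid plexus medians 0.046 and 1.35.

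The third comparison asks what TMPyP4 treatment changed in AtrxdE2 mice, as the difference of both log2 ratios over wild type. Ttr differed by 4.99 log2 units, Sostdc1 by 1.95, Folr1 by 1.86, Kcne2 by 1.53, Kl by 1.43, Clic6 by 1.42 and Calml4 by 1.39, all higher in the treated pool. Guca1a with 1.89, Cap1 with 1.89 and Serpini1, which encodes the neuronal protease inhibitor neuroserpin, with 1.57 were the other highest genes. Lower in the treated pool were Cast (-1.84), R3hdm1 (-1.61), Col6a1 (-1.54), Xlr3b (-1.45; -2.01 in the authors' value table), Zcchc7 (-1.36), Gtl2 (-1.24), the chemokine receptor gene Ccr4 (-1.22), Chl1 (-1.15), Slfn8 (-1.14) and the immunoglobulin gene Igh6, now Ighm (-0.97). The SD of the 500 genes nearest in signal was 0.31 for Xlr3b, which lay at their percentile 0.1. Atrx was 0.32 higher (1.18 in the authors' value table, percentile 92.5), Xlr4b had -0.36 (percentile 1.5) and Daxx -0.23 (percentile 18.7).

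By the 2-fold rule 40 probes were higher and 49 lower in AtrxdE2+TMPyP4 than in AtrxdE2. Unnamed probes made up 71.4% of those lower and 27.5% of those higher, against 26.3% of all measured probes. Among lists, 10 of 46 had a median in the outer 5%, against 2.3 expected by chance for independent genes. The choroid plexus list had a median difference of 1.31 (SD 1.24, percentile 100), with all 14 genes above 0 (1.93 in the authors' value table), and the meninges list 0.20 (SD 0.30, percentile 99.4), with 11 of 14 above 0. Unfolded protein and stress response genes had 0.17 (SD 0.23, percentile 99.1), with Ddit4 at 0.58 and Herpud1 at 0.56, and oxidative phosphorylation genes 0.095 (SD 0.19, percentile 97.52), with Sdhb at 0.54. Lower in the treated pool were oligodendrocyte precursor genes (median -0.17, SD 0.22, percentile 0.9, with Bcas1 at -0.55 and Pdgfra at -0.47) and glutamate receptor and postsynaptic density genes (median -0.078, SD 0.28, percentile 1.46, with 24 of 33 below 0, Gria1 at -0.86 and Grin2b at 0.43). CA1 genes had -0.21 (SD 0.33, percentile 1.91, with Wfs1 at -0.36), and blood genes -0.38 (SD 0.37, percentile 0.01, with all 4 below 0 and S100a9 at -0.93; the median was -1.22 in the authors' value table). Glucocorticoid response genes had -0.13 (SD 0.38, percentile 2.08), from Cdkn1a at -0.44 to Fkbp5 at 0.82, with a median of 0.076 under median centring, and cell cycle genes -0.073 (SD 0.25, percentile 1.47), with Dcx at -0.56 and Pcna at 0.56 and a median of 0.067 among probes above the median signal. In the authors' value table the lists of CA1 (percentile 7.44), glucocorticoid response (10.9) and oxidative phosphorylation (95.8) left the outer 5%, as did the meninges list among probes above the median signal (91.6) and with plain subtraction (96.73). CA1 also left with median centring (4.91) and plain subtraction (4.03), and cell cycle genes against unmatched random lists (3.48). Glucocorticoid response left with plain subtraction (3.6) and among probes above the median signal (median -0.092). Oligodendrocyte genes had a median difference of 0.095 (percentile 84.0).

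Preset lists in the middle 95% of random lists for this difference were immediate early genes (median 0.045, percentile 74.2, with Ier5 at 1.20, Homer1 at 0.55 and Btg2 at -0.65), CaMKII and calcium signalling (median -0.016, percentile 26.9, with Camk2g at 0.29 and Cacna1h at -0.89) and heme metabolism (median 0.14, percentile 96.2, with Hmox2 at 0.45). Imprinted genes also lay there (median 0.023, percentile 57.0, with Nap1l5 at 0.72 and Herc3 at 0.65), as did Atrx and its partners (median -0.12, percentile 4.35, with Setdb1 at -0.44 and Cbx5 at -0.27). Against unmatched random lists, heme metabolism (98.86) and Atrx and its partners (1.56) lay in the outer 5%. Above background in the treated pool but not in AtrxdE2 were Suclg2, at least 4.02-fold higher, Cldn2 with 2.3, Steap1 with 2.21, Catsper3 with 2.06 and the water channel gene Aqp1 with 1.71. Of these, Cldn2, Steap1 and Aqp1 belong to the choroid plexus list but were outside its measured members. Above background in AtrxdE2 only were Slc5a4b, at least 1.5-fold lower in the treated pool, Usp36 with 1.43, Zfa (now Zfa-ps) with 1.33, Rnf26 with 1.31 and Cd180 with 1.29. Median centring gave 89 probes higher and 60 lower, the authors' value table had 576 and 467, and the Cy3 channels compared directly gave 227 and 309.

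The arrays were then set against each other. Across measured probes, which are not independent replicates, the log2 ratios of both mutant pools over wild type correlated with Pearson's r = 0.151 and Spearman's rho = 0.109. Unchanged groups simulated with 1 shared wild-type value per probe gave r = 0.494, and with separate wild-type values r = 0.003. The simulation gave all channels the same spread, which fixes both values in advance, so they do not test the pools. In the data the wild-type channels differed between arrays with an SD of 0.27 and the Cy3 channels with 0.41. The covariance of the observed log2 ratios was 0.00604, against 0.0334 in the simulation with a shared value. Ttr, Mgp and an unnamed probe were at least 2-fold higher on both arrays, and an unnamed probe was lower on both, against 0.0174 and 0.00279 probes expected from independent lists. Part of this overlap may come from the shared wild type and dye orientation. For Ttr the wild-type signals were 44.3 and 219.4 on the arrays, against 352.6 in AtrxdE2, so its rise in AtrxdE2 depends on which wild-type value is used. Of the 16 probes at least 2-fold changed in AtrxdE2, 13 (81.3%) lay closer to wild type in the treated pool, Xlr3b and Mbp among them. The reverse selection also gave a high share: of 40 probes changed in the treated pool, 38 (95%) lay closer to wild type in AtrxdE2. No interval is given because the probes come from 1 pair of arrays.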

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

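Blood genes had medians at opposite ends of the random lists on the arrays, 0.33 over wild type in AtrxdE2 and -0.12 in AtrxdE2+TMPyP4, a median difference of -0.378 in the 4 measured genes. It stood out because the list median moved the opposite way in each group, and with 1 array per group the difference was not tested. S100a9 had 0.74 and -0.20, S100a8 had 0.42 and -0.071, and Ngp had 0.24 and -0.022. Alas2 was below 0 on both arrays, at -0.093 and -0.17. No haemoglobin gene was among the 4. In the authors' value table the medians were 1.065 and -0.31 and the median difference -1.215, and the AtrxdE2+TMPyP4 median lay at percentile 4.82, inside the middle 95%. No explanation was weighed for this list.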

How the results depend on the processing

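Local background, the runs without the choroid plexus and meninges lists, and plain subtraction for lists, overlap and the correlation were chosen after seeing the data. The counts of 2-fold probes moved with the background and normalization steps, which several alternatives change together; the cause was not tested. For AtrxdE2 over wild type the total of 16 became 367 in the authors' value table, 351 with plain subtraction (176 higher, 175 lower), 47 with local background (24 and 23) and 242 at 1.5-fold. For AtrxdE2+TMPyP4 over wild type the total of 40 became 92 with median centring, 454, 431, 460 (447 and 13) and 272, with the authors' table, plain subtraction, local background and 1.5-fold in that order. For the difference between mutant pools the total of 89 became 149, 1043, 1055, 654 (601 and 53) and 675 in the same order, and 536 with the Cy3 channels compared directly. The correlation between arrays was 0.451 with median centring; its cause was not tested. Overlap on the higher side was 6 with median centring, 32 in the authors' table, 21 with plain subtraction and 20 at 1.5-fold, and on the lower side 0, 2, 3 and 10. The SD between wild-type channels was 0.343 among probes above the median signal. The number of lists in the outer 5% for the difference fell to 6 among those brighter probes, where 40 lists could be tested. Among lists in the outer 5%, medians that changed sign were those of CA1 (0.116) and microglial genes (0.201) in AtrxdE2+TMPyP4 over wild type and of glucocorticoid genes (0.076) in the difference, with median centring, and of cell cycle genes in both (0.123 and 0.067) among brighter probes; the causes were not tested. Medians of lists inside the middle 95% changed sign too, such as that of Atrx and its partners in AtrxdE2+TMPyP4 over wild type (0.184 with median centring). Over named genes and lists, the authors' value table left 89 results on their side of the rule, took 21 past it and 5 back. Median centring left 95, took 5 past it and 12 back, and changed the sign of 3. No paired analysis was possible because each group has 1 array. Signal over background limits choroid plexus genes such as Folr1, with wild-type signals of 3.6 and 2.0 above blanks that varied with an SD of 1.23 and 0.92.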

Other observations

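Several lists lay near 0 while the choroid plexus list was high in the treated pool, unlike those of meninges (median 0.67), striatum (-0.50) and thalamus and habenula (0.15). Ependymal genes had medians of -0.007 over wild type in AtrxdE2 and -0.049 in AtrxdE2+TMPyP4, endothelial genes 0.066 and 0.10, dentate granule neuron genes -0.033 and 0.031, interneuron genes -0.014 and -0.037, and genes of neocortex and subiculum -0.059 and 0.028. Genes for G-quadruplex helicases and binders had 0.043 and -0.015, and cytosolic ribosomal protein genes -0.011 and -0.03. With the main normalization none of these medians lay in the outer 5% of random lists; with median centring that of interneurons in AtrxdE2+TMPyP4 did (percentile 1.25).

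Of the tests below, the one with a second choroid plexus list was written before its result was seen, and all others after the pattern was seen; those of dye bias, dilution, mixed wild-type RNA and the spread between arrays were also revised after their first values were seen. The first pattern is the choroid plexus signal in the AtrxdE2+TMPyP4 pool. A single faulty Ttr spot is argued against by the list without Ttr, whose 13 genes had a median of 1.32 (percentile 100). Choroid plexus tissue in the dissected pool may account for the pattern. A second list of 28 measured choroid plexus genes, none held by another list, had a median of 0.163 (percentile 100), with 26 above 0, against 0.013 in AtrxdE2 (percentile 70.8). All were above background in wild type, as the rule for measured probes requires. Whether its genes are also expressed in the meninges, whose list was high in this pool too (median 0.67), was not tested. In the first list, by which the pattern was seen, the abundant marker Ttr reached a signal of 60792, Folr1 284.2 and Kl 329.0. These signals restate the pattern and are no further support. TMPyP4 acting on hippocampal cells cannot be told apart from tissue in the pool, since there is 1 treated pool.

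The second pattern is that Xlr3b and Atrx lay nearer wild type in the treated pool. With no offset, 1.0% of the 500 probes nearest in signal to Xlr3b differed between arrays by at least its -1.98 log2 units, against 0.4% with the main normalization (-1.45, SD 0.31) and with median centring. For Atrx the shares were 3.0% (1.22), 12.2% and 24.0%, so the spread between the arrays stays open for Atrx, and for Xlr3b because its share was under 1% with the main normalization and median centring but not with no offset. RNA of the wild-type pool mixed into the treated pool, at the 90.7% that Xlr3b needs, would let no gene fall below a log2 ratio of -0.141 if ratios carried no dye bias. With no offset, 1 of 46 lists had a median below this bound by more than its SD. It was the striatal list, at -0.695 (SD 0.52, against -0.154 in AtrxdE2), and it did not pass with median centring or among brighter probes. A single list that fails in some settings, with no dye swap, cannot decide this, so mixing at that share stays open. A share of 81.5%, which lies 1 SD of probes near Xlr3b away and has a bound of -0.295, cannot be told apart from none because no list lay below that bound by more than its SD. Single genes did lie below both bounds with no offset, such as Rxrg at -1.588, Col6a1 at -1.367, Cast at -1.304 and Gtl2 at -1.212. They were picked as the lowest genes of 1 array without a dye swap, so they do not decide either share. A response to TMPyP4 stays open and was not tested.

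The third pattern is the low oligodendrocyte signal in both mutant pools. Dilution that lowers all hippocampal cell types alike is argued against in AtrxdE2 with the main normalization only. The medians of 6 of 6 lists of these cell types, astrocytes at 0.006 among them, lay above the oligodendrocyte median by more than their SD. Dentate granule neurons did not with median centring, plain subtraction or the authors' table. Dilution by tissue that itself holds such cell types would leave their lists high, so it stays open. In AtrxdE2+TMPyP4 only 3 of 6 did (astrocytes 0.114, dentate granule neurons 0.031 and microglia -0.112, but not CA1 at -0.253), so dilution stays open there. Dye bias common to both arrays cannot be told apart from a change in both pools without a dye swap, and the difference between pools, where it drops out, was 0.095 (SD 0.28, percentile 84.0). Less white matter in the mutant dissections cannot be told apart from fewer or less mature oligodendrocytes, since either would leave the precursor list nearer 0. With the main normalization it lay nearer 0 than the oligodendrocyte list in both pools, with medians of 0.012 in AtrxdE2 and -0.159 in AtrxdE2+TMPyP4 (percentile 0.13). In AtrxdE2+TMPyP4 the order turned with median centring (-0.221 for precursors against -0.145). There the lists lay close in the authors' value table (-0.3 against -0.335) and with plain subtraction (-0.323 against -0.357). An effect of the genotype also stays open, untested.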
